A study of Mus musculus with 10 samples.

How the data were processed

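Hematopoietic progenitor cells were isolated from the bone marrow of mice that carried Lewis lung carcinoma tumours. The mice had received vehicle or 60 mg/kg of BMS-595, an inhibitor of the protein kinase CK2, for 2 weeks, per the labels' protocols. There were 5 libraries of the vehicle group and 5 of the inhibitor group, called CK2i below. The sample titles of the vehicle group read untreated cells, and the group is named here by the protocols. Libraries were made from total RNA with a stranded kit and sequenced as 75 base paired reads on a NextSeq 500, per the labels' protocols. The labels number the replicates of each group but do not say that each came from a separate mouse, so p-values measure the spread between these samples, which may in part be technical.

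The deposited table holds, for each library, estimated counts per gene and FPKM values. Per the submitters' processing notes, Bowtie2 and RSEM 1.2.31 were used with the genome build mm10, and DESeq2 is also named. The transcript annotation, the strand setting of the quantification and any filter are not given in the sources used here. The deposited estimated counts are whole numbers that sum to 34127674 to 43636152 per library, so RSEM's expected counts appear rounded by the authors before deposit. The deposited FPKM values were computed by the authors with RSEM; they scale each count by transcript length and sequencing depth. RSEM shares reads that fit several genes between them by its model. Values of near-identical copies are therefore uncertain one by one, which holds here for Hspa1a and Hspa1b, Hba-a1 and Hba-a2, Hbb-bs and its neighbour, Ugt1a6a and Ugt1a6b, clustered histone genes and immunoglobulin segments. The 7SL RNA copies Rn7s1 and Rn7s2 have identical counts in all 10 libraries. Genes that overlap on opposite strands can be told apart only if strand was used in counting.

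The table lists 38887 Ensembl gene identifiers and 2 empty lines, which were left out. Symbols and coordinates came from the GENCODE M21 mouse annotation of GRCm38, the assembly also named mm10, and 37570 identifiers matched. The 1317 others kept their identifier as a name and held at most 0.536% of the counts of any library. A count of 0 in all libraries was found for 15952 genes. The annotated structural RNAs, led by Rn7s1, Rn7s2 and Rn7sk, took 6.28% to 7.55% of the counts of a library. Mitochondrially encoded genes were not analysed here. No pair of libraries in a group agreed within sampling noise: the chi-square per degree of freedom over genes ran from 10.96 to 72.9.

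The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on the deposited counts, with TMM scaling and group as the only term. Genes were kept by filterByExpr with its default minimum count of 10, which left 14346. Tests were two-sided with Benjamini-Hochberg adjustment over those genes, and an adjusted p under 0.05 was the threshold. Standard errors of log2 fold changes were obtained as the fold change divided by the square root of the F statistic. Values per library are CPM with TMM scaling, and group values are means ± SD. At an average biological coefficient of variation of 14.2% and at least 34127674 counts per library, the spread between libraries and not counting error sets the precision for all but the lowest genes. The same script was tested on simulated counts for the real genes, of which 14216 were tested. It recovered 94% of 50 genes raised 2-fold, 96% of 50 lowered 2-fold, 76% of 50 raised 1.5-fold and 78% of 50 lowered 1.5-fold, with 5 false calls. The simulated genes varied independently, without differences between libraries that many genes share. These rates test the script and do not give the error rates for the real libraries.

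Gene lists for cell types, pathways and RNA quality, 40 in all, were fixed before the data were examined. Of these, 39 had at least 3 tested members. Each was tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 39 lists. Camera compares a list with all other genes. Beside it stand camera with the correlation estimated for each list and fry, which asks whether a list's members move, on balance, one way. A list score is the mean over members of log2 CPM minus the vehicle mean. Differences of list scores were tested with exact permutation tests, two-sided, over all 252 splits of 10 libraries into 5 and 5, or all splits of the libraries named. Some lists share genes, among them Kit, Cybb, Csf3r, Cebpb, Pmaip1, Hspa1a and Psmb8.

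The genes named were taken by a rule also fixed then. It takes 22 genes named whatever their test says, which are the CK2 subunits, the C/EBP family, Ikzf1, Spi1, Notch1, Hes1, Mpo, Elane, Camp, S100a8, S100a9, Csf1r, Kit and Cd34. It adds the 12 largest rises and 12 largest falls among genes with adjusted p under 0.05 and at least 1 FPKM in the higher group, leaving out gene models without a name. It also adds the 4 members of smallest p of each list past its test, and up to 3 members with adjusted p under 0.05 of each other list. In all 145 genes were taken, and the text prints those that illustrate each group. Some genes and 1 list are not reported here.

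The alternatives were DESeq2's size factors, scaling by total count only, no filter on low counts, DESeq2 1.42.0, limma voom, limma on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with at least 1 FPKM in 5 libraries, the replicate number as a block, 1 surrogate variable (sva 3.50.0), other thresholds, and leaving out each library in turn. After the data were seen, the fit with CK2i libraries 1, 3 and 4 only and a fit with the trend of each library on transcript length and GC content removed were added. The table of the authors' own test results that the plan allowed for was not used here.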

Results

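Transcript levels were measured by RNA sequencing in bone marrow hematopoietic progenitor cells of mice with Lewis lung carcinoma, a transplantable mouse tumour. There were 5 libraries from mice given vehicle and 5 from mice given the CK2 inhibitor. CK2 is a constitutively active serine/threonine kinase with catalytic subunits encoded by Csnk2a1 and Csnk2a2 and a regulatory subunit encoded by Csnk2b. Total estimated counts ranged from 37569160 to 43636152 in vehicle libraries and from 34127674 to 40811539 in CK2i libraries. The 10 genes with most counts took 10.37% ± 0.20 and 10.33% ± 0.43 of the counts. The single comparison that the design holds, CK2i against vehicle, asks how the inhibitor altered transcript levels of these progenitors in a study of myeloid differentiation.

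In CK2i libraries, the lists of neutrophil granule genes and of monocyte genes were higher than in vehicle libraries, and that of megakaryocyte and platelet genes was lower, by camera with a preset correlation between genes (adjusted p = 7.44e-06 or less) but not with the correlation estimated for each list (0.744 each). Of the genes in the C/EBP list, 4 of 7 rose, and the list missed the threshold. Mpo, the peroxidase of primary granules, rose from 2840 ± 713 to 4380 ± 814 CPM (SD, n = 5 per group). Cebpe, a transcription factor of late granulocyte differentiation, rose from 9.38 ± 2.81 to 17.0 ± 4.90 CPM. Tubb1, the platelet beta tubulin, fell from 260 ± 31.1 to 141 ± 55.6 CPM, and Jchain, the joining chain of secreted immunoglobulins, fell from 592 ± 73.2 to 308 ± 66.2 CPM. In edgeR's quasi-likelihood test, 1892 of 14346 genes passed an adjusted p of 0.05, 922 of them higher and 970 lower in CK2i. A fold of at least 2 was reached by 146 of the higher and 82 of the lower genes. The groups did not overlap for 1569 genes (10.9% of those tested), where chance gives 0.79% on average over all splits. Genes that vary together can be apart in far larger numbers in a single split, so this contrast does not exclude chance.

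The count depended on the model and on single libraries. It was 30 with 1 surrogate variable, which had a correlation of 0.70 with the group, 1139 with the replicate number as a block, 1091 by limma on log2(FPKM + 1) and 3168 with DESeq2, which was run without the filterByExpr filter. It was 446 without CK2i 5, 617 without CK2i 2, 3198 without CK2i 3, 458 without vehicle 1, 758 without vehicle 3, 528 without vehicle 4 and 546 without vehicle 5. The calls present in all 10 fits that left out 1 library numbered 364, with 150 higher and 214 lower. CK2i 2 and CK2i 5 stood apart on the first principal component, at 43.26 and 43.68, where CK2i 1, 3 and 4 lay between -4.10 and 12.48 and the vehicle libraries between -29.62 and -9.37. With CK2i 1, 3 and 4 as the only treated libraries, a fit added after the data were seen, 175 genes passed, 169 of them among the 1892.

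**Figure D1:**
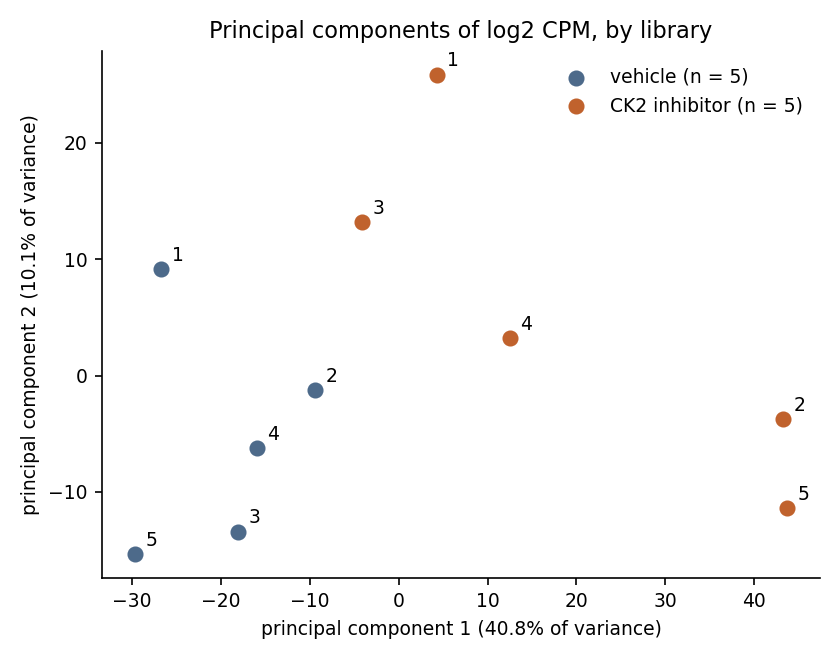
Principal components of log2 CPM over the tested genes, with component 1 (40.8% of variance) on the horizontal and component 2 (10.1%) on the vertical axis, in arbitrary units. Each point is a library with its replicate number; CK2i 2 and 5 lie at 43.26 and 43.68 on component 1, apart from the other 8 libraries.

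The genes of the inhibited kinase itself did not pass the test. Csnk2a1 (ENSMUSG00000074698; GRCm38 chromosome 2, 152226839 to 152281852) was at 256 ± 7.14 CPM in vehicle and 241 ± 10.4 CPM in CK2i, a log2 difference of -0.09 ± 0.04 (SE, edgeR adjusted p = 0.137). For Csnk2a2 and Csnk2b the log2 differences were 0.03 ± 0.05 (adjusted p = 0.647) and 0.03 ± 0.04 (adjusted p = 0.591). The inhibitor acts on the protein, and transcript levels do not measure its activity. The list of the 3 subunit genes did not pass camera (adjusted p = 0.977).

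In the list of the C/EBP family, which takes in factors that direct myeloid gene expression, 4 of 7 members rose and none fell. Cebpa (ENSMUSG00000034957; chromosome 7, 35119293 to 35121928) rose by 0.38 ± 0.10 log2 (adjusted p = 0.0340), Cebpb by 0.63 ± 0.14 (0.0224), Cebpd by 0.64 ± 0.15 (0.0283) and Cebpe by 0.86 ± 0.24 (0.0426). Each was above all vehicle libraries in 4 of the 5 CK2i libraries. Cebpg, Cebpz and Ddit3 differed by -0.03, -0.01 and -0.10 and did not pass. The count adjusted over the list alone was also 4. As a list the family missed the camera threshold (adjusted p = 0.0772, and 0.744 with an estimated correlation), while the score of each of the 5 CK2i libraries lay above those of all vehicle libraries. Of the 4 calls, Cebpa was kept in 5, Cebpb in 6, Cebpd in 4 and Cebpe in 3 of the 10 fits that left out 1 library.

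Myeloid transcription factors moved in both directions. Of 26 members of that list, 7 rose, 4 of which are the C/EBP genes above, and 2 fell (8 and 2 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.104). Gfi1, a repressor needed for neutrophil development, rose by 0.91 ± 0.18 (adjusted p = 0.0187), and Spi1, which encodes PU.1, rose by 0.52 ± 0.15 (adjusted p = 0.0428; 3 of the 10 fits). Stat5a, a transducer of cytokine receptor signals, fell by 0.23 ± 0.05 (adjusted p = 0.0178), in all 10 fits. Csf1r, the receptor of macrophage colony-stimulating factor, was at 73.8 ± 14.0 and 103 ± 20.4 CPM and did not pass (adjusted p = 0.0629). Ikzf1, the gene of Ikaros, differed by -0.03 ± 0.06 (adjusted p = 0.753). In the list of Ikaros family members and partners, Ctbp1 alone of 13 passed, with a fall of 0.19 ± 0.05 (adjusted p = 0.0394, 1 adjusted over the list alone, camera adjusted p = 0.881).

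Primary granule genes, listed here for the promyelocyte stage, rose as a group: 13 of 15 passed upward, none downward, with a median log2 difference of 0.68 (15 upward adjusted over the list alone). Mpo (ENSMUSG00000009350; chromosome 11, 87793581 to 87804413) rose by 0.63 ± 0.18 (adjusted p = 0.0451), Elane, neutrophil elastase, by 0.84 ± 0.24 (0.0426), Ms4a3, a marker of granulocyte and monocyte progenitors, by 0.89 ± 0.18 (0.0181), and Hp, haptoglobin, by 0.86 ± 0.15 (0.0128). Hp and Ms4a3 passed in all 10 fits without 1 library, Mpo and Elane in 2 of them. The list's camera adjusted p was 9.56e-08, and it was 0.744 with an estimated correlation. List scores were 1.04 and 1.02 in CK2i 2 and 5, against 0.68, 0.25 and 0.59 in CK2i 1, 3 and 4 and -0.50 to 0.38 in vehicle libraries.

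Genes of secondary and tertiary granules and late neutrophils rose in 11 of 22 tested members and fell in none, with a median of 0.70 (12 adjusted over the list alone). Chil3, a secreted chitinase-like protein, rose from 1.04 ± 0.420 to 7.23 ± 5.68 CPM (log2 2.78 ± 0.57, adjusted p = 0.0188). Wfdc21 rose from 1.36 ± 0.496 to 5.73 ± 2.02 CPM (adjusted p = 0.00745), and Cybb, the catalytic chain of the phagocyte NADPH oxidase, from 27.3 ± 6.39 to 69.7 ± 26.3 CPM (adjusted p = 0.0159). S100a8, a calcium-binding protein abundant in mature neutrophils, rose from 8.97 ± 4.18 to 28.2 ± 17.8 CPM (adjusted p = 0.0404; 4 of the 10 fits without 1 library, and 0.253 with CK2i 1, 3 and 4 only). Its partner S100a9, at 6.60 ± 4.47 and 12.4 ± 7.85 CPM, and the antimicrobial peptide gene Camp, at 0.696 ± 0.466 and 1.09 ± 0.720 CPM, did not pass (adjusted p = 0.204 and 0.376). The camera adjusted p of the list was 7.44e-06, and 0.744 with an estimated correlation. Scores were 1.19 and 1.10 in CK2i 2 and 5, against 0.13 to 0.76 in CK2i 1, 3 and 4 and -0.48 to 0.61 in vehicle libraries, so that 3 of the 5 CK2i libraries lay above all vehicle libraries.

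Monocyte and macrophage genes rose in 6 of 34 members and fell in none, with a median of 0.47 (12 adjusted over the list alone). Cd14, the lipopolysaccharide co-receptor, rose by 1.15 ± 0.19 (adjusted p = 0.0104, all 10 fits), Cd68 by 0.64 ± 0.13 (0.0191) and Itgam, the integrin chain CD11b, by 0.86 ± 0.23 (0.0364). The camera adjusted p was 7.44e-06, and 0.744 with an estimated correlation. Scores of 0.85 and 0.88 in CK2i 2 and 5 stood above 0.18, 0.04 and 0.42 in CK2i 1, 3 and 4 and -0.21 to 0.21 in vehicle libraries, so that 3 of the 5 CK2i libraries lay above all vehicle libraries. With 1 surrogate variable the list's direction turned (adjusted p = 0.863). Genes associated with granulocytic myeloid-derived suppressor cells rose in 9 and fell in 2 of 31 members (10 and 5 adjusted over the list alone) without passing camera (adjusted p = 0.201). Among them Ncf1, a subunit of the phagocyte oxidase, rose by 0.64 ± 0.13 (adjusted p = 0.0190). The dendritic cell list did not pass (adjusted p = 0.904), with Ccr9 the 1 member called, at -0.80 ± 0.21 (adjusted p = 0.0356; also 1 adjusted over the list alone). Nor did the list for eosinophils, basophils and mast cells (adjusted p = 0.856), in which 3 members rose, among them Hdc, histidine decarboxylase, by 0.54 ± 0.15 (adjusted p = 0.0431), and 1 fell (4 and 2 adjusted over the list alone).

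**Figure D2:**
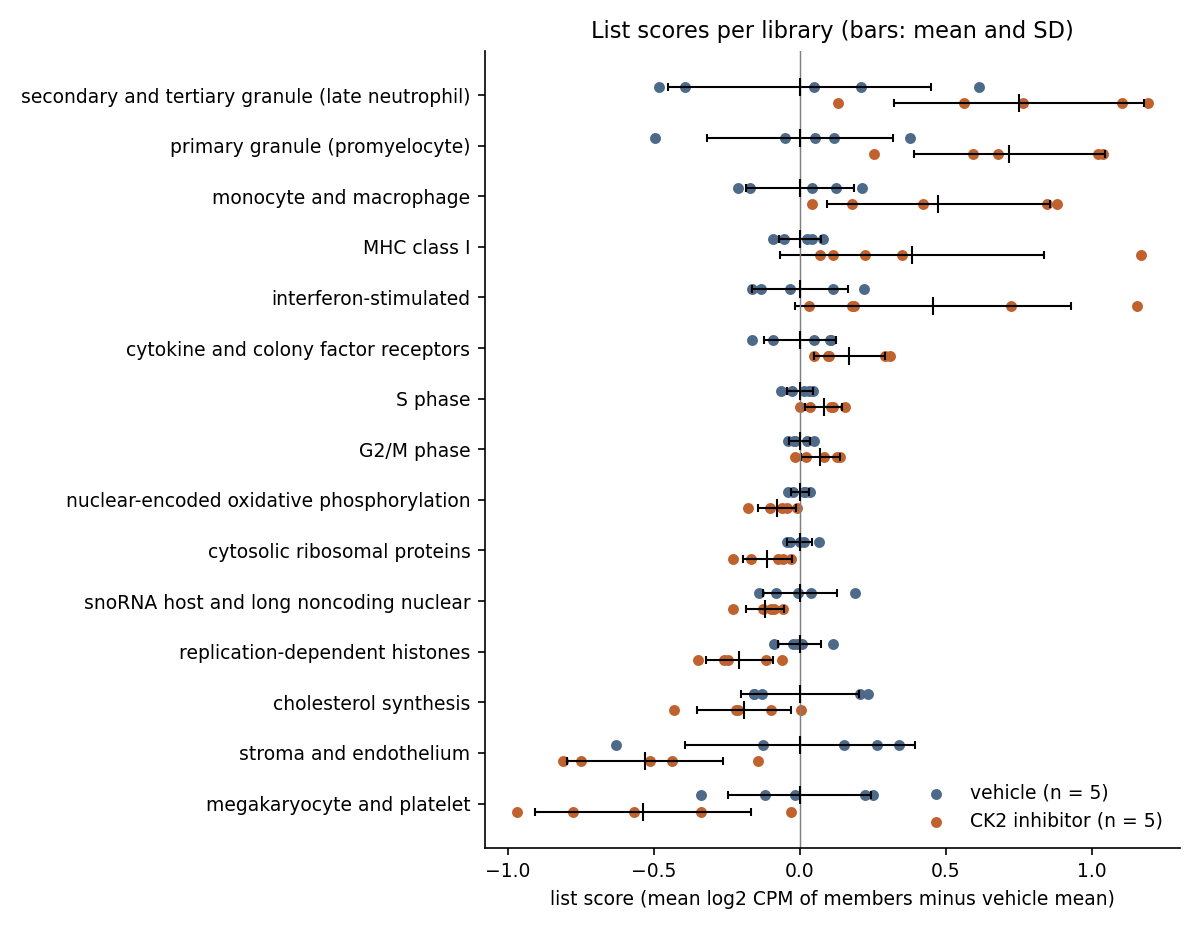
Scores of the 15 lists that passed camera with the preset correlation, as mean log2 CPM of members minus the vehicle mean on the horizontal axis, 1 row per list. Points are libraries, and vertical ticks and bars are group means and SD (n = 5); scores of the primary granule list reach 1.04 and 1.02 in CK2i 2 and 5, and the MHC class I score of CK2i 5 is 1.17.

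Megakaryocyte and platelet genes fell in 7 of 25 members and rose in none, with a median of -0.54 (17 downward adjusted over the list alone). Tubb1 fell by 0.88 ± 0.23 (adjusted p = 0.0347), Treml1, a platelet granule receptor, by 0.75 ± 0.20 (0.0375), Pdzk1ip1 by 0.93 ± 0.23 (0.0325) and the small GTPase gene Rap1b by 0.47 ± 0.12 (0.0322). Each was kept in 3 or 4 of the 10 fits without 1 library. The camera adjusted p was 3.05e-07, and 0.744 with an estimated correlation. Scores were -0.97 and -0.78 in CK2i 2 and 5, against -0.34, -0.03 and -0.57 in CK2i 1, 3 and 4 and -0.34 to 0.25 in vehicle libraries. Stromal and endothelial genes fell in 3 of 25 members and rose in none (4 downward adjusted over the list alone; median -0.54). These were Apoe, apolipoprotein E, by 0.71 ± 0.08 (adjusted p = 0.00241), the collagen gene Col5a1 by 0.93 ± 0.15 (0.00888) and Pecam1 by 0.25 ± 0.07 (0.0429). The list's camera adjusted p was 0.00322, and 0.744 with an estimated correlation. Scores were -0.75 and -0.81 in CK2i 2 and 5, against -0.51, -0.14 and -0.44 in CK2i 1, 3 and 4 and -0.63 to 0.34 in vehicle libraries. Only CK2i 2 and 5 lay below all vehicle libraries.

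Stem and multipotent progenitor genes fell in 5 of 26 members and rose in none (9 down and 1 up adjusted over the list alone), and the list did not pass camera (adjusted p = 0.104). Kit, the stem cell factor receptor (ENSMUSG00000005672; chromosome 5, 75574916 to 75656722), fell from 269 ± 16 to 225 ± 19.2 CPM (log2 -0.26 ± 0.06, adjusted p = 0.0302). Gfi1b, a transcriptional repressor active in the erythroid and megakaryocytic lineages, fell by 0.55 ± 0.12 (adjusted p = 0.0248), and Txnip by 0.34 ± 0.08 (0.0296). Cd34 was at 179 ± 29.4 and 197 ± 14.8 CPM and did not pass (adjusted p = 0.388). Erythroid genes moved in both directions, with 8 up and 7 down of 37 (10 and 10 adjusted over the list alone) and no call by camera (adjusted p = 0.649). Slc4a1, the band 3 anion exchanger of red cells, rose from 24.5 ± 10.3 to 78.6 ± 24.6 CPM (adjusted p = 0.0127). The globin genes Hbb-bs and Hba-a2 rose by 1.45 ± 0.22 and 1.10 ± 0.17 (adjusted p = 0.00765 and 0.00863), and Slc25a37, the mitochondrial iron importer mitoferrin, by 0.52 ± 0.07 (0.00537). All 4 passed in the 10 fits without 1 library.

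In the lymphoid lists few members passed. Jchain (ENSMUSG00000067149; chromosome 5, 88519809 to 88527891) fell by 0.94 ± 0.14 (adjusted p = 0.00611), in all 10 fits without 1 library, and Cecr2 rose by 0.47 ± 0.14 (0.0493), the other call among 21 B lymphoid genes (camera adjusted p = 0.264). Adjusted over the list alone, 1 B lymphoid gene passed. Of 20 T and NK genes 2 fell, Lat, an adaptor of T cell receptor and platelet collagen receptor signals, by 0.92 ± 0.21 (adjusted p = 0.0232) and the granzyme gene Gzmb by 0.67 ± 0.19 (0.0446; also 2 adjusted over the list alone), and the list did not pass (adjusted p = 0.0570). Among named genes that passed with at least 1 FPKM in the higher group (gene models without a name left out), immunoglobulin variable segments made up 7 of the 12 largest falls, from Ighv9-1 at -3.76 ± 0.77 (adjusted p = 0.0188) to Igkv8-30 at -1.53 ± 0.45 (0.0484). Reads of such segments are shared between close copies.

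**Figure D3:**
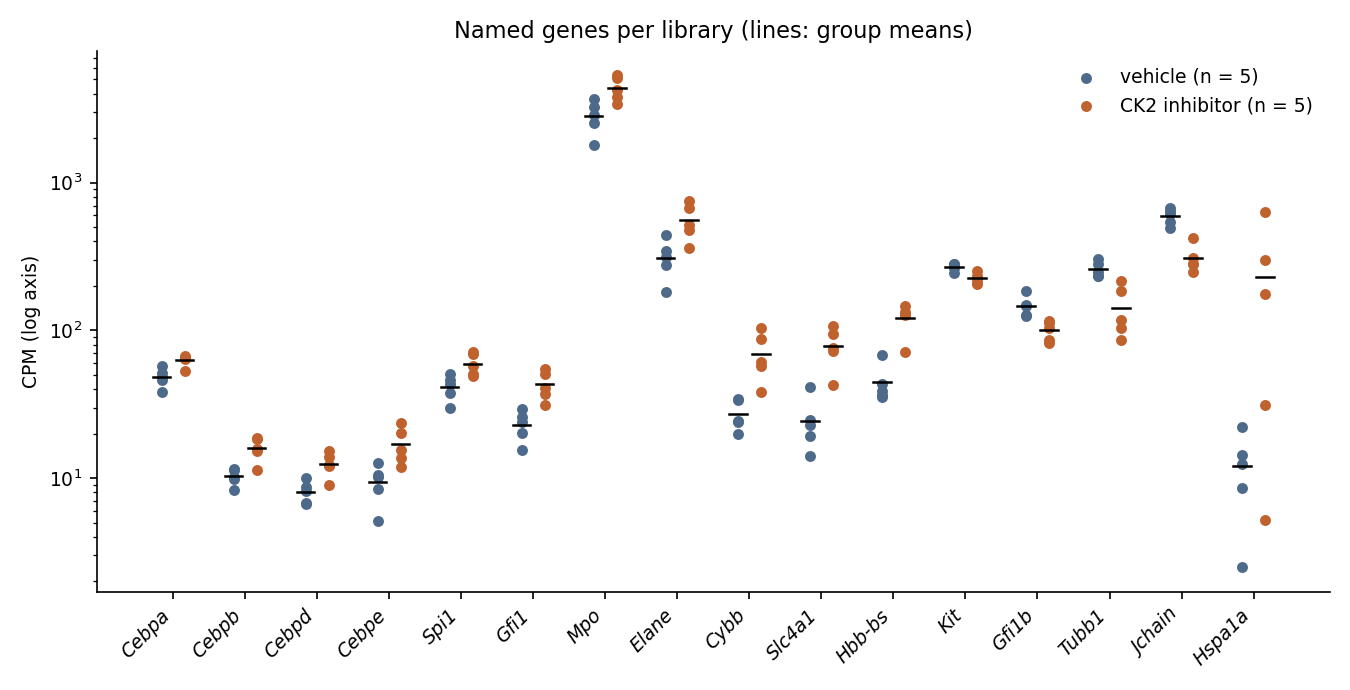
CPM of 16 named genes on a logarithmic vertical axis, 1 position per gene, with vehicle libraries on the left and CK2i libraries on the right of each. Points are libraries and black lines group means (n = 5 each); Mpo averages 2840 and 4380 CPM, and Hspa1a spans 5.16 to 630 CPM among CK2i libraries.

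The largest rise among genes that passed with at least 1 FPKM in the higher group was that of Hspa1a, a stress-inducible heat shock protein (ENSMUSG00000091971; chromosome 17, 34969190 to 34972156), at 12 ± 7.21 and 229 ± 254 CPM (log2 4.25 ± 1.04, adjusted p = 0.0301). Its CK2i libraries 1 to 5 held 5.16, 31, 302, 177 and 630 CPM. The near-identical Hspa1b rose by 3.81 ± 1.00 (adjusted p = 0.0359). They passed in 5 and 4 of the 10 fits without 1 library and missed the threshold with CK2i 1, 3 and 4 only (adjusted p = 0.0805 and 0.0892). Among 20 heat shock and chaperone genes 3 rose and 1 fell, over all genes and adjusted over the list alone, with a median of -0.02, and the list did not pass (adjusted p = 0.881). Apol11b followed at 0.248 ± 0.104 and 4.29 ± 6.62 CPM (adjusted p = 0.0259), with 16.1 CPM in CK2i 5 and 0.630 to 1.87 CPM in the other CK2i libraries. All 5 CK2i libraries lay above all vehicle libraries for Glt1d1 (log2 1.93 ± 0.27, adjusted p = 0.00555), Hs6st2, a heparan sulfate sulfotransferase (1.92 ± 0.29, 0.00763), and the GTPase gene Rhou (1.90 ± 0.32, 0.0119). Among named genes with the same limit of 1 FPKM, the largest falls outside the immunoglobulin segments were those of Fam220a (-2.25 ± 0.39, adjusted p = 0.0120), Gml2 (-2.08 ± 0.34, 0.0104), Sardh, sarcosine dehydrogenase (-2.04 ± 0.26, 0.00424), Tceal3 (-1.93 ± 0.34, 0.0130) and the tubulin gene Tubb2b (-1.88 ± 0.42, 0.0235).

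Interferon-stimulated genes rose in 9 of 50 members and fell in none, with a median of 0.43 (9 adjusted over the list alone). Oas1g, an oligoadenylate synthetase, rose by 1.05 ± 0.21 (adjusted p = 0.0180), and Ifi204 by 1.51 ± 0.40 (0.0364). The camera adjusted p was 1.44e-06, and 0.744 with an estimated correlation. Scores were 1.16 in CK2i 5 and 0.72 in CK2i 2, against 0.19, 0.18 and 0.03 in CK2i 1, 3 and 4 and -0.165 to 0.22 in vehicle libraries, so that only CK2i 2 and 5 lay above all vehicle libraries. MHC class I genes passed camera (adjusted p = 0.00135, and 0.744 with an estimated correlation) with all 15 log2 differences above 0 and a median of 0.45, while none of the 15 passed alone, over all genes or adjusted over the list alone. Tapbp, the peptide loading factor tapasin, was at 152 ± 8.34 and 208 ± 55.0 CPM (adjusted p = 0.0533). The score of CK2i 5 was 1.17 those of the other CK2i libraries were 0.07 to 0.35, and those of vehicle libraries -0.09 to 0.08. The MHC class II list did not pass (adjusted p = 0.881), nor did any of its 10 members.

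Receptors of cytokines and colony-stimulating factors rose in 8 and fell in 4 of 30 members (14 and 5 adjusted over the list alone), with a median of 0.19. Csf3r, the granulocyte colony-stimulating factor receptor, rose by 0.70 ± 0.16 (adjusted p = 0.0243), Csf2rb, the shared beta chain for interleukin-3 and GM-CSF, by 0.58 ± 0.13 (0.0239) and Ifnar1 by 0.26 ± 0.05 (0.0180), while Il1rl1, the interleukin-33 receptor, fell by 0.32 ± 0.07 (0.0258). The camera adjusted p of 0.0335 became 0.744 with an estimated correlation. It also missed the threshold without vehicle 1 (0.0627), vehicle 5 (0.0587), CK2i 2 (0.0527) or CK2i 5 (0.0519), and with CK2i 1, 3 and 4 only (0.102).

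Cell cycle lists shifted by small amounts in opposite directions. S phase genes rose in 4 of 44 members (2 adjusted over the list alone; median 0.08; camera adjusted p = 0.00135, and 0.744 with an estimated correlation), among them Hells, a chromatin remodeller, by 0.27 ± 0.06 (adjusted p = 0.0201) and the ribonucleotide reductase gene Rrm2 by 0.34 ± 0.08 (0.0296). In the list of G2 and M phase genes 4 rose and 3 fell of 59 (1 and 2 adjusted over the list alone; median 0.07; camera adjusted p = 0.00380, and 0.744 with an estimated correlation). Ncapd2, a condensin subunit, rose by 0.20 ± 0.05 (adjusted p = 0.0340), and Cenpa, the centromeric histone H3 variant, fell by 0.25 ± 0.04 (0.0104). Replication-dependent histone genes fell in 17 of 40 members and rose in none (27 adjusted over the list alone; median -0.21; camera adjusted p = 1.35e-09, and 0.744 with an estimated correlation). Hist1h1e and Hist1h1d, linker histone genes, fell by 0.22 ± 0.04 and 0.26 ± 0.05 (adjusted p = 0.0138 and 0.0150).

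Genes of protein synthesis and respiration shifted downward by little. Cytosolic ribosomal protein genes had negative log2 differences in 73 of 74 members, with a median of -0.11, and 5 passed, among them Rpl37a at -0.18 ± 0.04 (adjusted p = 0.0279). Nuclear-encoded genes of oxidative phosphorylation were negative in 71 of 73, with a median of -0.08, and 6 passed, among them Sdhb, a succinate dehydrogenase subunit, at -0.18 ± 0.04 (adjusted p = 0.0261). None of either list passed when adjusted over the list alone. Host genes of small nucleolar RNAs and nuclear noncoding RNAs fell in 4 of 10 members (4 adjusted over the list alone), with Gas5 at -0.28 ± 0.08 (adjusted p = 0.0413) and Epb41l4aos at -0.40 ± 0.09 (0.0247). Camera gave adjusted p of 1.94e-09, 1.44e-06 and 0.0453 for these lists, and 0.744 for each with an estimated correlation. Log2 differences followed transcript length, with a median of -0.08 for 547 genes of up to 1000 bases and 0.03 for 3767 genes over 4000 bases. Spearman's rho of length with each library's deviation from the mean of all 10 was 0.36 and 0.23 in CK2i 2 and 5, against -0.13, -0.08 and 0.03 in CK2i 1, 3 and 4 and -0.37 to -0.04 in vehicle libraries. With the length and GC trend removed, the adjusted p was 0.00113 for ribosomal proteins, 0.104 for oxidative phosphorylation and 0.136 for the host genes. The host genes also missed the threshold without vehicle 4 (0.0602), vehicle 5 (0.0974), CK2i 2 (0.0507), CK2i 3 (0.0568) or CK2i 5 (0.0608).

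Cholesterol synthesis genes had negative log2 differences in 24 of 25 members, with a median of -0.23. Over all genes 2 members fell and 1 rose. Tm7sf2, a sterol reductase, fell by 0.32 ± 0.09 (adjusted p = 0.0452), a call kept in 0 of the 10 fits that left out 1 library. Adjusted over the list alone, 3 fell and 1 rose. The camera adjusted p was 0.00103, and 0.744 with an estimated correlation. With 1 surrogate variable the list's direction turned (adjusted p = 0.979). Glycolysis genes changed in 14 of 25 members without a call for the list (adjusted p = 0.277). Of these 9 rose, among them Gapdh by 0.22 ± 0.04 (adjusted p = 0.0184), Gpi1 by 0.36 ± 0.08 (0.0206) and Pfkfb4 by 0.60 ± 0.11 (0.0139), and 5 fell. Adjusted over the list alone, 13 rose and 6 fell.

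Signalling and cell death lists did not pass, but single members did. Jag1, a Notch ligand, rose from 0.619 ± 0.0805 to 1.61 ± 0.309 CPM (adjusted p = 0.00392) and Dtx4 by 0.78 ± 0.18 (0.0266), whereas Dtx3 fell by 0.35 ± 0.07 (0.0212). Notch1 was at 41.3 ± 8.70 and 59.7 ± 15.3 CPM (adjusted p = 0.0739) and its target Hes1 at 1.5 ± 0.181 and 1.25 ± 0.172 CPM (adjusted p = 0.215). In the Notch list 4 rose and 1 fell of 25 (8 and 2 adjusted over the list alone; camera adjusted p = 0.247). Pmaip1, which encodes the pro-apoptotic protein NOXA, rose from 6.33 ± 0.798 to 12.9 ± 1.69 CPM (adjusted p = 0.00203). Diablo, which encodes an antagonist of inhibitor of apoptosis proteins, fell by 0.29 ± 0.04 (adjusted p = 0.00537). Both passed in the 10 fits without 1 library and with CK2i 1, 3 and 4 only. In the BCL2 family list 1 rose and 4 fell of 30 (2 and 4 adjusted over the list alone; camera adjusted p = 0.997), and among p53 targets 3 rose and 2 fell of 30, over all genes and adjusted over the list alone (camera adjusted p = 0.997). Il6, the interleukin-6 gene, fell from 1.72 ± 0.356 to 0.721 ± 0.292 CPM (adjusted p = 0.0224) and Ccl3 by 0.43 ± 0.10 (0.0297), 2 of the 3 falls among 28 NF-kB targets (3 up and 5 down adjusted over the list alone; camera adjusted p = 0.856).

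Of the other lists, none passed camera. Members that rose and fell numbered 2 and 3 of 25 for JAK/STAT feedback and targets (camera adjusted p = 0.856) and 1 and 1 of 22 for Wnt and beta-catenin (0.889). They numbered 3 and 0 of 30 for the unfolded protein response (0.264), 1 and 0 of 38 for MYC targets and ribosome biogenesis (0.173), and 2 and 0 of 24 for immediate early and dissociation genes (0.881). The 2 rises in this last list were Hspa1a and Hspa1b, given above, and its median was -0.06. Adjusted over the list alone, the same counts were 3 and 3, 1 and 1, 3 and 0, 0 and 0, and 2 and 0. Foxo3, a transcription factor restrained by AKT, fell by 0.20 ± 0.04 (adjusted p = 0.0185), Fzd7, a Wnt receptor, fell by 0.33 ± 0.05 (0.00957), and the co-receptor gene Lrp5 rose by 0.42 ± 0.10 (0.0289). Calr, a chaperone of the endoplasmic reticulum, rose by 0.19 ± 0.05 (adjusted p = 0.0421), and Hk2, hexokinase 2, by 0.44 ± 0.11 (0.0358).

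By the tests that allow for correlation between genes, no list passed: camera with an estimated correlation gave 0 of 39 at an adjusted p of 0.05, and fry gave 0 of 39, with 0 and 13 lists at an unadjusted p under 0.05. Of the 126 named genes that passed, 39 did so in all 10 fits that left out 1 library and 22 with CK2i 1, 3 and 4 only.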

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

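A library was singled out where its gap to the nearest library of its group, divided by the range of the 5 libraries, passed Dixon's 95% critical value. Chance gives about 1 such group in 20, which is 19 of the 374 groups tested, and 17 were found. The tests of the MHC class I and interferon-stimulated lists below were chosen after the result was seen.

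Among treated libraries, CK2i 5 was highest for Apol11b (ratio 0.920, 16.1 CPM against 0.630 to 1.87 in the others), for Psmb8, an immunoproteasome subunit (ratio 0.711, 260 against 149 to 181 CPM), for the MHC class I score (ratio 0.745, 1.17 against 0.07 to 0.35) and for the MHC class II score (ratio 0.772, 0.87 against -0.28 to -0.01). CK2i 3 was lowest for the globin genes Hbb-bs (ratio 0.732, 71.9 against 127 to 147 CPM) and Hba-a2 (ratio 0.783, 50.9 against 76.6 to 83.7 CPM). It was highest for Apoe (ratio 0.711, 64.5 against 47.4 to 52.4 CPM), Igkv8-16 (ratio 0.716, 1.49 against 0.317 to 0.649 CPM) and the immediate early and dissociation score (ratio 0.733, 0.71 against -0.03 to 0.17). CK2i 2 was highest for Ighv1-39 (ratio 0.717, 28.2 against 4.68 to 11.3 CPM) and the Wnt and beta-catenin score (ratio 0.779, 0.08 against -0.03 to 0.00), and CK2i 4 was lowest for Cebpa (ratio 0.749, 53.4 against 63.7 to 67.1 CPM).

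Among vehicle libraries, vehicle 5 was highest for Hbb-bs (ratio 0.741, 68.0 against 35.1 to 43.7 CPM) and for the noncoding RNA Zfas1 (ratio 0.743, 105 against 92.1 to 95.5 CPM). Vehicle 3 was highest for Tceal3 (ratio 0.720, 3.04 against 1.64 to 2.03 CPM) and lowest for Oas1g (ratio 0.716, 3.56 against 5.55 to 6.34 CPM). Vehicle 2 was highest for Ighv1-18 (ratio 0.820, 9.29 against 2.39 to 3.63 CPM).

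CK2i 5 held the highest scores of both the MHC class I and the interferon-stimulated genes, so that library alone is a candidate explanation for their rise. Without it the MHC class I score of CK2i 1 to 4 still exceeded the vehicle mean by 0.19 ± 0.07 (SE; exact permutation p = 0.0159, two-sided), which argues against CK2i 5 as the only source, although it raised the mean difference to 0.38. The interferon-stimulated score exceeded the vehicle mean by 0.28 ± 0.17 (exact permutation p = 0.0952), and an effect of the treatment and of CK2i 5 cannot be told apart for this list with 4 libraries left. Camera with the preset correlation still passed both lists without CK2i 5 (adjusted p = 1.57e-04 and 2.05e-05), over a range of 2.41e-04 to 0.00339 and 1.90e-08 to 2.81e-05 for the other libraries left out, while with an estimated correlation neither passed even with all libraries (0.744 each). Whether CK2i 5 came from a mouse with another exposure to interferon is not recorded in the labels used here.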

How the results depend on the processing

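The fit with CK2i 1, 3 and 4 only and the removal of the length and GC trend were chosen after the result was seen. All 1892 calls kept their sign under each scaling, filter, tool and left-out library and with CK2i 1, 3 and 4 only, except that 1888 did with 1 surrogate variable and 1673 were tested on FPKM. These genes were called in the same libraries, so a kept sign follows largely from that choice and is no independent support. The count of genes was 3168 (1708 higher, 1460 lower) with DESeq2, 1091 (558, 533) and 1081 (555, 526) by limma on log2(FPKM + 1) and log2(FPKM + 0.1), 30 (15, 15) with 1 surrogate variable, 664 (421, 243) with a fold of at least 1.5 and 3837 (1998, 1839) at an adjusted p under 0.1. The fit with CK2i 1, 3 and 4 only gave 175 (73, 102). The surrogate variable had a correlation of 0.99 with the first component and 0.70 with the group, so it takes up part of the group difference. FPKM tests held 12052 genes. The DESeq2 fit took in 22935 genes, without the filterByExpr filter, so its count differs from the main one in both test and filter. Other causes were not tested. Leaving out 1 library gave 446 to 3198 genes (182 to 1727 higher, 254 to 1471 lower), with 458, 758, 528 and 546 without vehicle 1, 3, 4 and 5, and 617, 3198 and 446 without CK2i 2, 3 and 5. DESeq2 size factors, total count scaling, no filter, limma voom and removal of the length and GC trend gave 1842, 1854, 1370, 1744 and 1964.

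In a count of 100 of the splits of the 10 libraries into 5 and 5, only the real split, 1 in number, gave as many as 1892 genes. The highest other split gave 352, and in it vehicle 2 and CK2i 3 had changed places. Every other split mixed vehicle and CK2i libraries on each side, so a difference between the groups would add to the spread within its sides. The real split thus ranked first of the 100 counted, but this rank cannot exclude chance as the source of the count.

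With the replicate number as a block, 1139 genes passed (457 higher, 682 lower), and 14 lists. Same-numbered libraries had correlations of their deviations of 0.23, 0.11, 0.07, 0.03 and -0.16. Not every library correlated best with its own number, though vehicle 1 and CK2i 1 matched each other best. Correlations over so few pairs cannot show whether equal numbers share a mouse, batch or day, which the labels do not say.

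Lists past the threshold numbered 0 with an estimated correlation and 0 by fry, against 15, and 13 to 17 with 1 library left out. With 1 surrogate variable 3 of the 15 kept their call, which were both granule lists and the histones. Of the list results under all settings, 566 kept direction and side of the threshold, 56 lost and 21 gained a call, and of the gene results 2133 kept both, 852 lost and 22 gained a call.

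Direction turned for 59 list and 20 gene results, nearly all without a call on either side; their cause was not tested. Turned log2 differences were -0.04 for Csnk2a2 with the length and GC trend removed and 0.00 for Hes1 by limma on log2(FPKM + 1). With 1 surrogate variable they were 0.07 for Cebpg, 0.05 for Cebpz, 0.16 for Ddit3, -0.01 for Notch1, -0.64 for Camp, -0.42 for S100a9, and -0.03 for H2-Q4 and for Nlrc5. With CK2i 1, 3 and 4 only they were 0.02 for Cebpg, 0.03 for Cebpz, 0.01 for Ddit3 and -0.14 for Camp. With 1 library left out, Cebpg ranged from -0.09 to 0.00, Cebpz from -0.03 to 0.01 and Ikzf1 from -0.07 to 0.01.

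Adjusted p of lists that turned with 1 surrogate variable were 0.357 for CK2 subunits, 0.863 for monocytes and macrophages, 0.0247 for eosinophils, basophils and mast cells, 0.556 for Ikaros, 0.402 for p53 targets, 0.750 for Wnt, 0.00128 for MYC targets, 0.979 for cholesterol synthesis, 0.0645 for MHC class II and 0.00954 for immediate early genes. With CK2i 1, 3 and 4 only they were 0.606 for CK2 subunits and for MYC targets, 0.498 for eosinophils, basophils and mast cells, 0.786 for Ikaros, 0.767 for p53 targets, 0.146 for MHC class II and 0.439 for immediate early genes. With the length and GC trend removed they were 0.920 for CK2 subunits, Ikaros, p53 targets and Wnt, and 0.941 for the BCL2 family. With the block they were 0.993 for eosinophils, basophils and mast cells, p53 targets and the BCL2 family. The list of p53 targets turned by fry (0.860). With 1 library left out, lists that turned ranged from 0.822 to 0.982 for CK2 subunits, 0.242 to 0.971 for dendritic cells, 0.0750 to 0.997 for erythroid genes, 0.378 to 0.946 for eosinophils, basophils and mast cells, 0.666 to 0.958 for Ikaros, 0.214 to 0.993 for heat shock, 0.822 to 0.996 for p53 targets, 0.818 to 0.999 for the BCL2 family, 0.256 to 0.996 for MHC class II and 0.168 to 0.958 for immediate early genes.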

Other observations

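All tests of this part and, apart from Pmaip1, the genes of its first 2 paragraphs were chosen after the values were seen, and so was the bound of an exact permutation p under 0.05 added to that of 2 SE, without which the tests of CK2i 2 and 5 and of the ribosomal proteins would have argued against these explanations; it was not asked of the S phase share, which needs a fall and not the absence of a rise. Among genes with a symbol that were called in all 10 fits that left out 1 library, those of smallest p were led by falls. Ptpn14, a protein tyrosine phosphatase of the Hippo pathway, fell from 13 ± 0.727 to 4.79 ± 0.653 CPM (log2 -1.44 ± 0.10, edgeR adjusted p = 1.60e-04, lower in 5 of 5 CK2i libraries). Trib2, a pseudokinase that promotes degradation of C/EBP alpha protein, fell by 1.26 ± 0.13, Amigo2 by 1.38 ± 0.13, Prelid2 by 1.02 ± 0.11, and the water and glycerol channel gene Aqp9 by 0.85 ± 0.09 (adjusted p = 0.00203 each). Tgfbr3, a co-receptor of TGF-beta, fell by 0.67 ± 0.07 and Tmcc2 by 0.61 ± 0.07 (adjusted p = 0.00203 each), and Plscr1 by 0.73 ± 0.08 (adjusted p = 0.00211) and Frat2 by 0.52 ± 0.06 (adjusted p = 0.00235). Dmxl2, with a rise of 0.84 ± 0.08 (adjusted p = 0.00203), and Pmaip1 rose.

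Erythroid genes moved in both directions, and the falls were not confined to regulators, since the list members Car1, Car2 and Aqp1 were also called lower. Gata1 and Nfe2, transcription factors of erythroid and megakaryocytic cells, fell by 0.47 ± 0.09 (adjusted p = 0.0178) and 0.38 ± 0.07 (0.0180), while the globin gene Hba-a1 rose by 1.04 ± 0.19 (0.0148). The erythroid transcription factor gene Klf1 differed by -0.23 ± 0.09 and did not pass (0.0993). Igha, the immunoglobulin A heavy chain gene, fell from 1810 to 1050 CPM (log2 -0.78 ± 0.14, adjusted p = 0.0130), while Ighm and Igkc, at -0.19 ± 0.37 (0.742) and -0.49 ± 0.21 (0.123), did not pass. Of 164 immunoglobulin variable and constant segments tested, 13 fell, none rose, and 119 had a negative log2 difference (median -0.40). Among genes induced by the aryl hydrocarbon receptor, Cyp1a1 fell by 1.69 ± 0.23 (adjusted p = 0.00491) and Nqo1 by 0.43 ± 0.13 (0.0477), while Tiparp rose by 0.42 ± 0.09 (0.0221) and Ugt1a6b by 2.15 ± 0.47 (0.0229). Of the feedback inhibitors of receptor tyrosine kinase signals, Spry4 fell by 1.75 ± 0.21 (adjusted p = 0.00392) and Spry1 by 0.72 ± 0.19 (0.0387), whereas Spry2 differed by 0.32 ± 0.11 (0.0650) and Dusp6 by -0.05 ± 0.15 (0.846).

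The rise of primary granule genes may reflect CK2i 2 and 5, other cells in the isolate, or the treatment. Mature neutrophils carry abundant S100a8 and S100a9 and little Mpo transcript, but the summed CPM gain of S100a8 and S100a9 was 1.63% of the gain of Mpo, which argues against added mature neutrophils as the source of the Mpo gain. It does not exclude that some were added, since the late neutrophil score also rose, by 0.75 ± 0.28 (SE). A lower share of megakaryocytic cells would raise all other cell types alike. The primary granule score rose by 0.76 ± 0.15 (SE) more than the mean score of 5 other cell type lists. The exact permutation p was 0.00794, two-sided, the smallest that 5 against 5 gives. The 5 lists were erythroid, B lymphoid, T and NK, dendritic cell, and eosinophil, basophil and mast cell. Of these, B lymphoid and T and NK scores fell (-0.17 and -0.32). Over the 5 lists, the excess argues against that share as the whole cause. The late neutrophil list (0.75 ± 0.28, SE) and the monocyte and macrophage list (0.47 ± 0.19, SE) also rose but were left out. An excess over them was not tested. Against the erythroid list alone the excess was 0.56 ± 0.27 (exact permutation p = 0.0794). That test was run first and widened after it missed 0.05. Taken singly, 4 of the 5 lists passed the exact permutation test. The lowest excess of these was 0.55 ± 0.17, for eosinophils, basophils and mast cells (exact permutation p = 0.00794). The highest was 1.04 ± 0.20, for T and NK cells (exact permutation p = 0.00794). CK2i 1, 3 and 4 alone exceeded the vehicle mean by 0.51 ± 0.19 (exact permutation p = 0.0714, where 0.0179 is the smallest possible), so CK2i 2 and 5 as the only source and an effect in all treated libraries cannot be told apart with 3 libraries. A shift in the mix of progenitors and a change within each cell both stay open, since bulk RNA was measured.

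The falls of histone, ribosomal protein and oxidative phosphorylation genes, which have short transcripts, could come from a length trend. Across 9537 genes, which are not independent replicates, Spearman's rho of the log2 difference with transcript length was 0.25, and rho of length with each library's deviation from the mean of all libraries was 0.36 and 0.23 in CK2i 2 and 5, the highest, and -0.37, in vehicle 2, to 0.03 in the other 8. With each library's trend on length and GC removed, the mean histone difference went from -0.206 ± 0.061 (SE) to -0.156 ± 0.044 (exact permutation p = 0.0159), which argues against the trend as its whole cause. Ribosomal proteins went from -0.111 ± 0.042 to -0.059 ± 0.027 (p = 0.0794, exact permutation), so that trend and treatment cannot be told apart at that spread. Oxidative phosphorylation went from -0.079 ± 0.032 to -0.032 ± 0.022 (p = 0.183, exact permutation), where the call ended because the difference itself shrank. The trend was fitted on the tested genes with the list members included, so its removal takes out part of their own shared fall. The shrinkage of these lists therefore cannot decide whether the trend was the cause. A lower share of cells in S phase would lower the S phase score, which instead lay 0.08 ± 0.03 above vehicle (exact permutation p = 0.0635 for a difference from 0), with 40 of 44 members positive (quartiles 0.03 and 0.12). For scores with the length trend left in, this argues against such a share as the cause of the histone fall of 0.21. The S phase score was not tested with the trend removed, so the share is not settled for the histone fall that remained then. The method by which total RNA was depleted or captured and an effect of the treatment stay open for the histones.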
